A study of Mus musculus with 48 samples.

How the data were processed

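Polyadenylated RNA was sequenced from preoptic area punches of female mice. Per the labels' protocols, males carrying Cre recombinase in gonadotropin-releasing hormone (GnRH) neurons were bred to females carrying a ribosomal protein, L10a, fused to green fluorescent protein (GFP) behind a floxed stop, so that GnRH neurons of the offspring carried tagged ribosomes. Each library came from the immunoprecipitate enriched for GnRH neuron RNA (IP) or from the GnRH-depleted supernatant. RNA was purified with the RNeasy Plus Micro kit with DNase treatment on the column, and libraries were made from poly(A) RNA with the SMARTer v4 Ultra Low kit, per the labels' protocols. That kit does not mark the strand, so reads from overlapping genes on opposite strands cannot be told apart.

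The deposited table gave estimated counts per gene for 23284 genes in 48 libraries, and 98.49% of its values were exactly whole numbers, with no tolerance applied. The other values carried decimals, as counters that divide shared reads give, and each value was rounded to a whole number before testing. Per the submitters' processing notes, the authors used FastQC 0.11.3, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff 2.1.1, HTSeq 0.6.1 and DESeq2 1.14.1 with the mouse build mm10. Which of these tools produced the counts, and with which annotation, is not given in the sources used here. Library totals ran from 28136004 to 55479453 counts (median 39654296), so a single read was worth far less than 1 CPM, the count scaled to a common library total. Where an interval is given for a count or a share, it is a 95% exact interval (Clopper-Pearson for shares, Poisson for counts), and it covers counting error only.

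Groups came from the labels of fraction, age and prenatal treatment, and replicate numbers from the labels. The labels call the replicates biological but do not say whether each is a single animal or a pool, so p-values measure the spread between these samples. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and each contrast was tested with the quasi-likelihood F test (robust dispersions) and Benjamini-Hochberg adjustment, calling genes at an adjusted p below 0.05. IP and supernatant were compared in 1 fit of all 46 libraries (16660 genes), and treatment and age within each fraction in a fit of its 23 libraries (15890 genes in IP, 16286 in supernatant). Standard errors of log2 fold changes were taken from the F statistic. CPM values were scaled to the library total, as mean ± SD where an SD is given. The 2 libraries from mice without Cre, 1 per fraction, entered no fit and have no test.

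For each contrast, 34 gene lists fixed beforehand were tested with camera (preset correlation 0.01, two-sided, at least 3 tested members, adjusted over the lists), with camera using an estimated correlation as the alternative. Fry, another test of gene lists, was run beside it. Genes were named by a rule. Per contrast it took the 10 genes with the largest rise and the 10 with the largest fall among those called, with a mean of at least 5 CPM in the higher group and with no overlap between the libraries of the groups. Where nothing passed, it took the 3 genes with the smallest p. It added 2 to 4 members with the smallest adjusted p of each list described, and Gnrh1, Gal, Kiss1r, Kiss1, Esr1, Esr2, Pgr and Xist in every contrast. Some genes that the rule also took are not reported here. Predicted genes were counted but not named. Comparisons, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined.

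The alternatives were DESeq2 1.42.0, RLE size factors, limma-voom with sample weights, no filter on low counts, a filter of 1 CPM in all libraries of a group, fits of the compared groups alone, a replicate block, a term for the libraries with the last 10 sample numbers, a covariate for glial transcripts in the IP, and leaving out each library in turn. Fits without the last 10 sample numbers, and without genes at least 2-fold higher in the IP of the mice lacking Cre, were added after the data had been seen. The test was checked on simulated counts with known changes. With 100 genes changed 2-fold, edgeR recovered 24 in the DHT contrast of young IP, 27 in that of adult IP and 77 in each DHT contrast of the supernatant. With 100 genes changed 4-fold it recovered 67, 64, 90 and 94 in the young IP, adult IP, young supernatant and adult supernatant. Simulated libraries of a fraction shared the spread and mean level of each gene across ages, while real adult IP replicates resembled each other less than young ones. The numbers recovered may therefore be too high for adult IP and too low for young IP.

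A depleted supernatant is by its name what an immunoprecipitation left behind, so the same replicate number within a condition was taken to tie an IP to its supernatant. The labels do not state this in words. Over 10922 genes, the deviations of same-numbered libraries from their group means correlated with medians of 0.15 to 0.28 in the 4 conditions, and 18 of 23 IP libraries correlated best with the supernatant of their own number. The lowest value for a same-numbered pair was -0.09. With this replicate block, 105 genes were called for the fraction by age interaction, against 173 without it. Coordinates are on GRCm38, the assembly also called mm10, from the GENCODE M21 annotation, counted from 1.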

Results

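The study asked which transcripts are enriched in GnRH neurons, the neurons that drive the reproductive axis, and whether prenatal androgen exposure alters them before puberty and in adulthood. Ribosome-bound RNA was captured from GnRH neurons of the preoptic area of female mice through GFP-tagged ribosomes (the IP), and the GnRH-depleted supernatant was sequenced beside it as the RNA of the surrounding tissue. Mice were young (prepubertal) or adult (collected in diestrus) and had been exposed before birth to vehicle or to dihydrotestosterone (DHT), an androgen that cannot be converted to estradiol. This gave 8 groups, 6 of them with 6 libraries and the pair of adult vehicle groups with 5 each. A further 2 libraries, 1 IP and 1 supernatant, came from young mice that carried the tag without Cre.

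Library totals ran from 28672561 to 47054031 counts in the 23 IP libraries and from 28136004 to 55479453 in the 23 supernatant libraries. Replicates resembled each other more in the supernatant than in the IP. The median correlation of log2 CPM within a group was 0.984 to 0.988 across genes in the supernatant, 0.92 in each young IP group, 0.83 in adult vehicle IP and 0.82 in adult DHT IP. Adult IP libraries also missed more genes. In vehicle mice 10.3% ± 2.08 of tested genes had no read in the adult IP (SD, n = 5) against 5.93% ± 1.38 in the young IP (n = 6; exact permutation test, two-sided, p = 0.00216, adjusted p = 0.00649 over 12 comparisons). In DHT mice the shares were 9.84% and 5.81% (exact permutation test, p = 0.00649, adjusted p = 0.0156), while supernatant groups lay between 0.555% and 0.849%.

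Gnrh1, which encodes the hormone that gives these neurons their name, was enriched 146-fold in the IP over the mean of the 4 conditions, at 5112 CPM against 34.8 CPM in the supernatant. Its log2 fold change was 7.19 ± 0.26 (SE; edgeR adjusted p = 4.14e-26). The gene lies on chromosome 14 from 67745181 to 67749439, on the plus strand. The enrichment was present in each condition, with log2 fold changes of 7.01 ± 0.50 in young vehicle, 6.85 ± 0.49 in young DHT, 7.80 ± 0.56 in adult vehicle and 7.11 ± 0.50 in adult DHT mice. Kiss1r, the receptor for the kisspeptins that excite GnRH neurons, was 2.21-fold higher in the IP (log2 fold change 1.15 ± 0.14, edgeR adjusted p = 6.33e-09). Gal, which encodes the neuropeptide galanin, was 1.60-fold higher (0.68 ± 0.13, edgeR adjusted p = 3.28e-05).

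**Figure D1:**
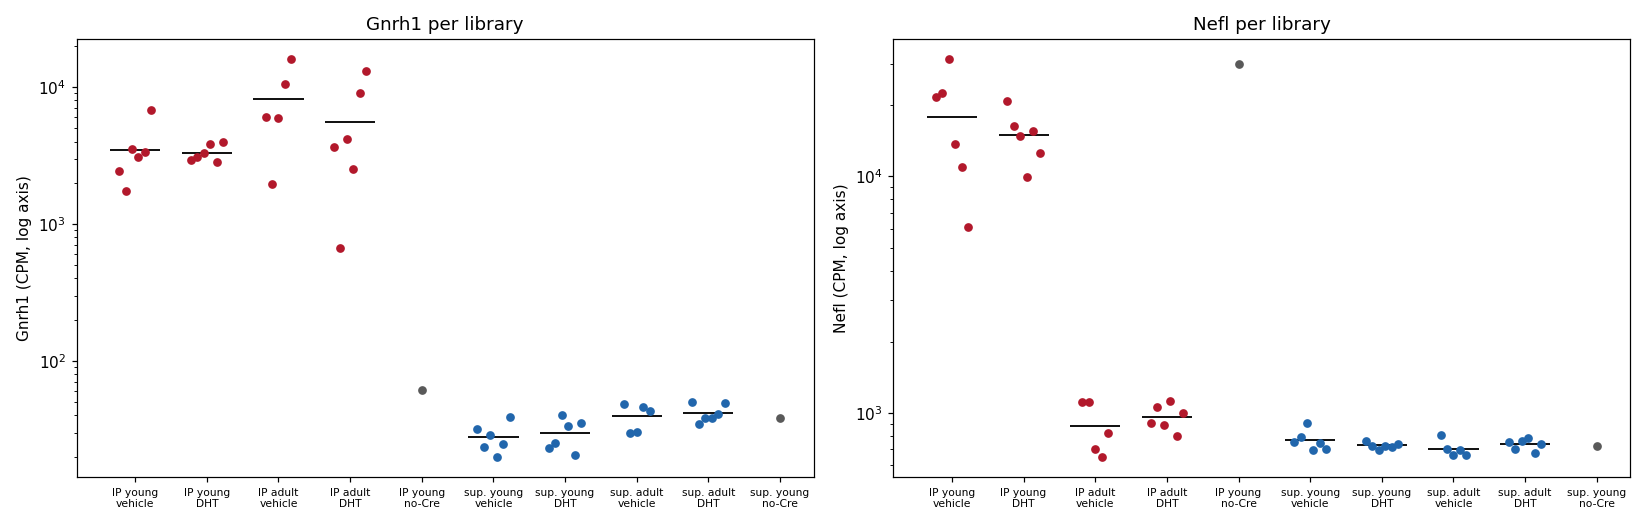
CPM of Gnrh1 and of Nefl in each library, on a log axis, by fraction, age and prenatal treatment; horizontal lines are group means and grey points are the 2 libraries from mice without Cre. Gnrh1 averaged 5112 CPM in the IP and 34.8 CPM in the supernatant and stood at 61.6 CPM in the IP without Cre, where Nefl reached 29998 CPM.

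Among other transcripts of the GnRH neuron list, Six6, a homeobox gene needed for GnRH neuron development, rose 7.16-fold in the IP (log2 fold change 2.84 ± 0.24, edgeR adjusted p = 1.93e-13) and Isl1, a LIM homeobox gene, rose 1.84-fold (0.88 ± 0.09). Of the list's 12 members, 7 were higher and 1 was lower over all genes, and 7 and 2 adjusted over the list alone (camera adjusted p = 0.000959). The list's adjusted p = 0.53 with an estimated correlation. The other transcripts named for the strongest enrichment were Tstd1 (log2 fold change 6.32), the chromatin and transcription regulators Bahcc1 (6.02), Bcor (5.40), Yeats2 (5.27) and Rai1 (5.11), Tnrc18 (5.66), the adhesion molecule gene Epcam (5.52), the arginase gene Arg1 (5.42) and the homeobox gene Otx1 (5.11 ± 0.21). Of these, Bahcc1, Bcor, Yeats2, Rai1 and Tnrc18 were also high in the IP of the control without Cre, with log2 ratios to its supernatant of 7.13, 7.07, 6.35, 6.79 and 6.45. Epcam and Otx1 were not, at -0.94 and -1.05, and the ratios of Tstd1 and Arg1 are not given here.

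Transcripts depleted from the IP included Lars2, a mitochondrial leucyl-tRNA synthetase gene (log2 fold change -4.32 ± 0.11), the neurotrophin receptor gene Ngfr (-3.47), the elongation factor gene Eef1a2 (-2.83), the nuclear long noncoding RNA Malat1 (-2.33) and Slc32a1, the vesicular GABA transporter gene (-2.12). Genes of the astrocyte list were lower in the IP: 10 of 14 fell and 0 rose over all genes, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0492, and adjusted p = 0.734 with an estimated correlation). Examples were Sox9 (-0.82) and Aldh1l1 (-0.58). Voltage-gated sodium, calcium and HCN channel genes fell in 10 of 29 cases, and in 9 adjusted over the list alone, among them Scn2b (-1.99) and Hcn2 (-0.92; camera adjusted p = 0.0210, and adjusted p = 0.53 with an estimated correlation). Genes of immature neurons fell in 6 of 18 cases, also adjusted over the list alone, with Marcksl1 at -1.02 and Sox4 at -0.90 (camera adjusted p = 0.0492, and adjusted p = 0.53 with an estimated correlation). Circadian clock genes fell in 8 of 18 cases, likewise adjusted over the list alone, with Hlf at -0.93 and Nr1d1 at -0.63 (camera adjusted p = 0.0210, and adjusted p = 0.541 with an estimated correlation). GABA system genes fell in 9 of 25 cases and rose in 4, likewise adjusted over the list alone, with Gabbr1 at -0.84 beside Slc32a1 (camera adjusted p = 0.0492, and adjusted p = 0.799 with an estimated correlation). With the replicate block, 3 more lists passed as lower: the potassium channels, the myelin genes and the immediate early genes, each at a camera adjusted p = 0.0492 against 0.0530, 0.0893 and 0.0656 without it, and none of them with an estimated correlation (adjusted p = 0.412, 0.616 and 0.412).

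Transcripts of ribosomal proteins rose together in the IP, 77 of 84 over all genes and 78 adjusted over the list alone, by a median log2 fold change of 0.66 (camera adjusted p = 4.06e-20, and adjusted p = 0.570 with an estimated correlation). Rpl10a itself, the gene of the tagged protein, rose 2.02-fold (log2 fold change 1.01 ± 0.10). Any reads from the tagged copy were not separated from those of the gene, so its rise cannot be assigned to the gene alone. Oxidative phosphorylation genes rose in 25 of 32 cases and fell in 1, and 27 and 1 adjusted over the list alone, with Uqcrc2 at 0.73 and Atp5c1 at 0.57 (camera adjusted p = 8.73e-06, and adjusted p = 0.570 with an estimated correlation). Esr1, the gene of estrogen receptor alpha, was lower in the IP, at -0.81 ± 0.27 (edgeR adjusted p = 0.0127). It was also lower in the IP of the control without Cre, at 6.28 CPM against 15.55 CPM in its supernatant. Pgr, the progesterone receptor gene, stood at 0.15 ± 0.12 and Kiss1 at 0.28 ± 0.21, neither past the threshold. Esr2, estrogen receptor beta, was at 1.44 CPM in the IP and 1.31 CPM in the supernatant. Its value of 0.20 ± 0.46 did not pass the threshold, and it turned to -1.22 with the replicate block (edgeR adjusted p = 0.0474).

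In all, edgeR called 7684 of 16660 genes between IP and supernatant, 4065 higher and 3619 lower in the IP, of which 562 and 1152 differed at least 2-fold. With the replicate block the split was 3530 higher and 5867 lower, and with voom 3650 and 6360. Of the 562 genes, 483 had values of GC content and transcript length, and 304 of these stayed at least 2-fold higher with the block. The control share and the DHT test of enriched genes below rest on the 562 and were not repeated on a set taken with the block. By condition, 3643 genes were called in young vehicle, 3324 in young DHT, 4002 in adult vehicle and 3576 in adult DHT mice. In fits of the compared groups alone, 2480 were called in adult vehicle and 2090 in adult DHT mice, voom called 5653 in young vehicle mice, and without the last 10 sample numbers 1584 were called in young DHT mice.

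The libraries without Cre set the background of the IP. There is 1 such library per fraction, with no test. Gnrh1 stood at 61.6 CPM in that IP (95% counting interval 59.0 to 64.4) and 38.2 CPM in its supernatant, a ratio of 1.61, against a mean of 3489 CPM in the IP of young vehicle mice. Kiss1r was 1.79-fold higher in the control IP and Gal 1.27-fold, against 1.97-fold and 1.31-fold in young vehicle mice, so at the age of the control both were about as high without tagged ribosomes. In adult vehicle mice they were 2.85-fold and 2.25-fold higher, with no control of that age. Of the 562 genes enriched at least 2-fold, 334 (59.4%, Clopper-Pearson interval 55.2% to 63.5%) were also at least 2-fold higher in the control IP than in its supernatant, against 12.4% of all tested genes. The share was 46 of 115 among genes enriched at least 4-fold, and 114 of 177 (64.4%) among those enriched at least 2-fold in each condition. In young vehicle mice, the age of the control, it was 357 of 527 genes enriched at least 2-fold (67.7%). Of the 1152 genes depleted at least 2-fold, 690 (59.9%) were also at least 2-fold lower in the control IP, against 15.98% of all tested genes. The astrocyte and circadian clock lists had median log2 ratios of -0.41 and -0.34 in the control pair, against -0.46 and -0.31 in Cre mice, so both were about as low without tagged ribosomes. Each such pair of medians sets 1 young pair of libraries against a mean over both ages. Myelin genes were also about as low (-0.27 against -0.33). The GABA system (-0.42 against -0.23), potassium channel (-0.43 against -0.26) and immediate early genes (-0.40 against -0.23) were lower in the control pair. The sodium, calcium and HCN channel and immature neuron lists had medians of -0.03 and 0.23 there, against -0.22 and -0.40. Of the lists that rose, ribosomal proteins had a median of 0.32 in the control pair against 0.66, oxidative phosphorylation 0.12 against 0.32 and the GnRH neuron list 0.06 against 0.56. Among neurofilament genes, Nefl, on chromosome 14 from 68083863 to 68089095, reached 29998 CPM in the control IP, 41.5-fold over its supernatant, and Nefh, on chromosome 11, was 35.0-fold higher. Nefm was 7.22-fold higher, but in the GENCODE M21 annotation Nefl lies within its span on the opposite strand. Reads of Nefl may therefore have been counted for Nefm. The annotation used for counting is not given, so this was not tested.

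**Figure D2:**
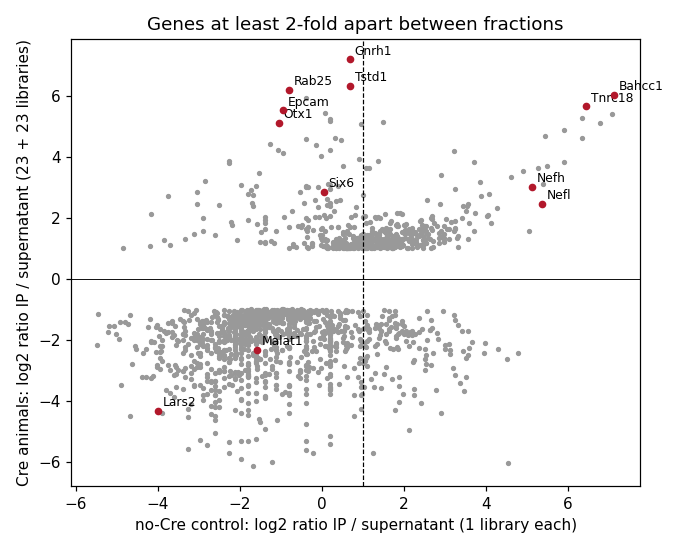
Log2 ratio of IP to supernatant in Cre mice (vertical axis, mean of the 4 conditions) against the same ratio in the single pair of libraries without Cre (horizontal axis), for the genes called and at least 2-fold apart in Cre mice; the dashed line marks a 2-fold excess in the control IP. Of the 562 genes above 0 on the vertical axis, 334 lie at or beyond the dashed line, while Gnrh1 lies left of it.

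Prenatal DHT was compared with vehicle in each fraction and age to ask whether androgen exposure before birth left a mark on these transcripts. In GnRH neuron IP of young mice, Gnrh1 averaged 3314 ± 472 CPM after DHT and 3489 ± 1756 CPM after vehicle (SD, n = 6 each), a log2 fold change of -0.10 ± 0.47. In adult IP it averaged 5536 ± 4658 CPM (n = 6) and 8109 ± 5389 CPM (n = 5), at -0.58 ± 0.49 (edgeR adjusted p = 0.821). Gal in adult IP stood at 126 CPM after DHT and 222 CPM after vehicle, at -0.84 ± 0.30 (edgeR adjusted p = 0.406). Kiss1r, Kiss1, Esr1, Esr2, Pgr and Xist passed the threshold in neither fraction at either age.

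The single transcript called between DHT and vehicle was Scube3, which encodes a secreted and membrane-bound EGF-domain protein and lies on chromosome 17 from 28142141 to 28174854. In adult IP it stood at 0.0407 ± 0.0324 CPM after DHT (n = 6) against 6.35 ± 4.69 CPM after vehicle (n = 5), a log2 fold change of -7.21 ± 1.11 (edgeR adjusted p = 0.0130), with each DHT library below each vehicle library. In young IP it averaged 3.66 CPM after DHT and 4.15 CPM after vehicle. The call was lost in a fit of the adult IP groups alone, with voom and with the replicate number as a block, and without adult DHT IP replicate 1 or 4 (edgeR adjusted p = 0.0592 and 0.0510). Of 100 splits of the adult IP libraries, 42 gave at least 1 gene, so chance was not excluded. It was the single gene called in adult IP, where 1318 genes had an unadjusted p below 0.05, against 794.5 expected by chance, DESeq2 called 151 and voom 0. The edgeR fit shared its spread estimate between ages. Adult IP replicates resembled each other less, with median correlations of 0.83 and 0.82 against 0.92 in young IP. Unadjusted p may therefore be too small in adult IP and too large in young IP, so such counts cannot be read against chance alone. In simulated counts for the DHT contrast of young IP, DESeq2 called 40 of 15690 unchanged genes, edgeR 4 and voom 1.

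In young IP edgeR called 0 genes and 239 had an unadjusted p below 0.05, against 794.5 expected by chance, under the same shared spread estimate. DESeq2 called 2 and voom 0. The genes with the smallest p, none past the threshold, were Gstm6 (log2 fold change 0.95, 40.1 against 20.8 CPM), Tmem59l (0.51) and Fam134a (0.48). Among the 562 IP-enriched genes, 0 were called at either age when adjusted over those genes alone, with 1 in young and 14 in adult mice below an unadjusted p of 0.05, 28.1 expected by chance. DESeq2 called 0 and 1 of them. Immediate early genes, which neurons induce on activation, leaned lower after DHT in young IP as a list (camera adjusted p = 5.16e-05, and adjusted p = 0.0819 with an estimated correlation), with Arc at -0.82 and Egr1 at -0.62. Cholesterol synthesis genes leaned higher (camera adjusted p = 0.000284, and adjusted p = 0.0507 with an estimated correlation), with Cyp51 at 0.75 and Fdps at 0.33. In adult IP, ribosomal protein genes leaned lower by a median of -0.31 (camera adjusted p = 1.44e-09) and neuropeptide genes by a median of -0.36 (camera adjusted p = 0.00159), each at an adjusted p = 0.960 with an estimated correlation. In these 4 lists 0 members were called, over all genes or adjusted over the list alone. By direction, fry called 0 lists between DHT and vehicle in young or adult IP, where camera called 6 and 2.

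In the supernatant edgeR called 0 genes at either age. In young mice 747 genes had an unadjusted p below 0.05 (814.3 expected by chance), DESeq2 called 1 and voom 0. In adults 338 did, DESeq2 called 0 and voom 1. The genes with the smallest p in young supernatant, not past the threshold, were Oas1c (-0.74), Cyp19a1, the aromatase gene (1.29, 0.567 against 0.227 CPM) and Stk10 (0.73). In adult supernatant they were Cdkn1b (0.46), Aldh1l2 (-0.66) and Akr1b3 (-1.08). Glutamate receptor genes leaned higher after DHT in young supernatant (median 0.19, camera adjusted p = 8.10e-09, and adjusted p = 0.311 with an estimated correlation), with 0 of 27 called over all genes or adjusted over the list alone. In adult supernatant members of that list such as Gria4 (-0.24) and Grm7 (-0.21) stood lower, not past the threshold. Of 31 lists camera called 13 in young supernatant (11 higher, 2 lower) and 5 in adult supernatant (1 higher, 4 lower). By direction, fry called 0 in both. The last 10 sample numbers were all young libraries of both treatments. Without them, 3 DHT and 4 vehicle libraries remained in young supernatant and 39 genes were called, 37 of them higher, such as Sc5d (0.84 ± 0.13) and Slc5a5 (0.67 ± 0.10), which stood at 0.37 and 0.26 in all libraries. With a term for those numbers 0 were called.

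The comparison of adults with young mice asked what changes between the prepubertal and the adult preoptic area. In the supernatant of vehicle mice (adult n = 5, young n = 6), Kiss1, the kisspeptin gene that marks preoptic neurons projecting to GnRH neurons, rose 4.71-fold, from 4.05 ± 1.18 to 19.5 ± 5.77 CPM (log2 fold change 2.24 ± 0.38, edgeR adjusted p = 0.000282). Mkrn3, a gene whose loss causes early puberty in humans, fell from 11.5 ± 2.60 to 2.16 ± 0.43 CPM (-2.44 ± 0.19, edgeR adjusted p = 5.58e-09). Il33, the alarmin made by mature oligodendrocytes and astrocytes, rose 7.22-fold to 72.6 CPM (2.85 ± 0.19). Pgr rose 1.24-fold (0.31 ± 0.08), while Esr1 at 0.63 ± 0.23 and Gnrh1 at 0.47 ± 0.18 did not pass the threshold (edgeR adjusted p = 0.0520 and 0.0647).

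Other large rises in that supernatant were Tuba1c (log2 fold change 4.73), Serpinb1a (2.71), the noncoding RNA Neat1 (2.12), Tnfaip6 (1.93), Wfs1 (1.35) and the metabotropic glutamate receptor gene Grm3 (1.30). Besides Mkrn3, the largest falls were Cldn14 (-3.66), Hbb-b2 (-2.98), Cnksr3 (-2.65), Beta-s (-2.38), Bmp4 (-2.17), Hba-a2 (-2.16), Alas2 (-2.10), Arpc1b (113 to 29.6 CPM) and Enpp6 (-1.93). Neuropeptide genes rose in 11 of 28 cases and fell in 0, over all genes and adjusted over the list alone, with Pdyn at 1.18, Tac2 at 1.16 ± 0.23 and Nts at 0.99 (camera adjusted p = 0.000306, and adjusted p = 0.283 with an estimated correlation). GABA system genes rose in 15 of 25 cases, 16 adjusted over the list alone, with Gabbr2 at 0.86 and Gabra5 at 0.60 (camera adjusted p = 1.35e-08, and adjusted p = 0.282 with an estimated correlation). Glutamate receptor genes rose in 12 of 27 cases, and adjusted over the list alone 14 rose and 1 fell, with Gria1 at 0.60 and Grm7 at 0.69 (camera adjusted p = 4.84e-06, and adjusted p = 0.283 with an estimated correlation).

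Myelin genes fell in 12 of 16 cases and rose in 1, over all genes and adjusted over the list alone, with Mobp at -1.91 ± 0.17, Cnp at -1.32 and Mbp at -1.11 (camera adjusted p = 2.55e-10, and adjusted p = 0.282 with an estimated correlation). Oligodendrocyte precursor genes fell in 5 of 10 cases, also adjusted over the list alone, with Gpr17 at -1.57 and Bcas1 at -1.53 (camera adjusted p = 2.31e-06, and adjusted p = 0.0904 with an estimated correlation). Genes of immature neurons fell in 6 of 18 cases, 7 adjusted over the list alone, with Marcksl1 at -0.96 and Sox4 at -0.72. This list kept its call with an estimated correlation (camera adjusted p = 1.87e-05, and adjusted p = 0.00266 with an estimated correlation). Of 4 blood genes 3 fell, among them Alas2 (camera adjusted p = 0.00120, and adjusted p = 0.259 with an estimated correlation). Oxidative phosphorylation genes fell in 14 of 32 cases and rose in 1, and 21 and 2 adjusted over the list alone (camera adjusted p = 2.31e-06, and adjusted p = 0.283 with an estimated correlation).

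After prenatal DHT (n = 6 each) genes named for vehicle mice also moved in the supernatant. Il33 rose by 2.79 and Kiss1 by 1.90 ± 0.37 on the log2 scale (edgeR adjusted p = 0.000935 for Kiss1), and Mkrn3 stood at -2.14, Cldn14 at -3.52 and Mobp at -1.58. Gnrh1 (0.51 ± 0.17), Esr2 (0.79 ± 0.28) and Pgr (0.22 ± 0.08) rose there (edgeR adjusted p = 0.0399, 0.0438 and 0.0401), while Gal at 0.04 ± 0.19 and Esr1 at 0.52 ± 0.22 did not pass the threshold (edgeR adjusted p = 0.899 and 0.0938). The precursor list fell in 5 of 10 cases, 7 adjusted over the list alone (camera adjusted p = 4.77e-08), and the immature neuron list in 7 of 18, 9 adjusted over the list alone (camera adjusted p = 6.08e-05). Both kept their calls, at an adjusted p = 0.0216 and an adjusted p = 0.00341 with an estimated correlation. GABA system genes rose in 5 of 25 cases, 8 adjusted over the list alone (camera adjusted p = 0.00235, and adjusted p = 0.700 with an estimated correlation). The supernatant gave 3301 called genes in vehicle mice (1641 higher, 1660 lower) and 3248 in DHT mice (1542 higher, 1706 lower). Of these, 708 higher and 1122 lower genes were called in both treatments, where 155 and 174 would be shared by independent lists, and 0 moved in opposite directions. Because the last 10 sample numbers were all young, the counts were also taken without them, at 3774 and 1121, and with a term for them, at 3612 and 1919, for vehicle and DHT mice. Both young groups held such libraries, so a shift tied to those numbers could add to the genes shared by the treatments. The overlap was not recounted without them.

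**Figure D3:**
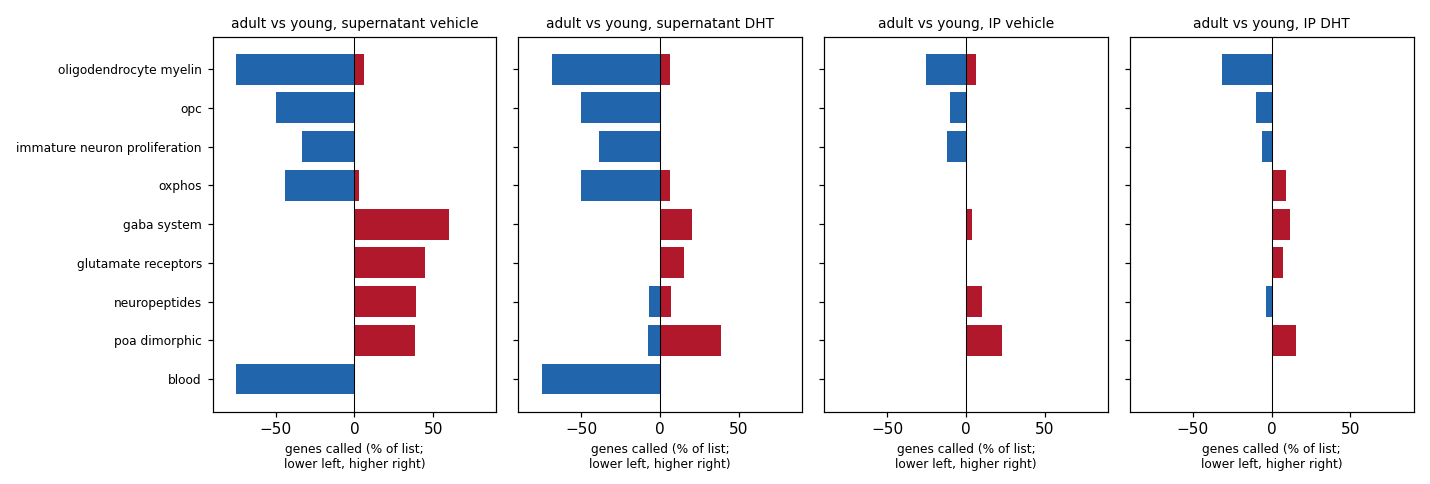
Percent of the tested members of 9 gene lists that were called higher (right, red) or lower (left, blue) in adult than in young mice, by fraction and prenatal treatment. In vehicle supernatant 15 of 25 GABA system genes were higher and 12 of 16 myelin genes were lower.

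In the IP of vehicle mice (adult n = 5, young n = 6), Kiss1 rose from 4.46 ± 1.79 to 27.1 ± 10.7 CPM (log2 fold change 2.63 ± 0.48, edgeR adjusted p = 0.00268), a rise also seen in the supernatant. Gal rose 2.88-fold, from 79.1 to 222 CPM (1.53 ± 0.30, edgeR adjusted p = 0.00499), and Scg2, a secretory granule gene, rose 3.35-fold (1.74 ± 0.26). Both also rose in the supernatant, Gal 1.73-fold (0.79 ± 0.20, edgeR adjusted p = 0.00659) and Scg2 2.02-fold (1.01 ± 0.20, edgeR adjusted p = 0.000978). Il33 (2.73 ± 0.43), Tuba1c (4.00), the autophagy gene Atg7 (2.16 ± 0.30) and Kalrn (1.61), which encodes a synaptic guanine nucleotide exchange factor, rose as well. Gnrh1 averaged 3489 CPM in young and 8109 CPM in adult IP, and its log2 fold change of 1.23 ± 0.50 did not pass the threshold (edgeR adjusted p = 0.178). The neurofilament light chain gene Nefl fell from a mean of 17780 ± 9209 CPM to 878.8 ± 220 CPM (-4.29 ± 0.31, edgeR adjusted p = 4.54e-09), and it was the gene that stood at 29998 CPM in the young control IP. Emilin1 (35.5 to 0.108 CPM), Cldn14 (6.49 to 0.0300 CPM), Bcl2l11 (5.93 to 0.0808 CPM), Srcin1 (-2.99), Kifc3 (-2.88) and Arpc1b (-2.83) fell too.

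Secretory genes rose in 6 of 28 cases and fell in 1 in that IP, and 12 and 2 adjusted over the list alone, with Syt4 at 1.11 and Scg3 at 0.75 higher and Cplx1 at -0.63 lower (camera adjusted p = 6.36e-05, and adjusted p = 0.295 with an estimated correlation). Neuropeptide genes rose in 3 of 29 cases, and 6 rose and 1 fell adjusted over the list alone, with Penk at 0.91 (camera adjusted p = 0.00184, and adjusted p = 0.447 with an estimated correlation). The GABA system list rose in 1 of 25 cases, Gabra3 at 1.13, and in 7 adjusted over the list alone (camera adjusted p = 1.31e-06, and adjusted p = 0.295 with an estimated correlation). Myelin genes, which GnRH neurons should lack, fell in 4 of 16 cases and rose in 1, and 8 and 1 adjusted over the list alone, with Mobp at -2.01 and Mbp at -1.27 (camera adjusted p = 1.31e-06, and adjusted p = 0.295 with an estimated correlation). Of 32 lists camera called 7 as higher and 5 as lower, 0 of them with an estimated correlation. Members of other cell type lists were lower too: the precursor gene Bcas1 (-1.24) and Birc5 of the immature neuron and proliferation list (-4.19) were called. The endothelial gene Cldn5 (-3.81) did not pass the threshold (edgeR adjusted p = 0.170). The mean log2 CPM of the astrocyte list differed little, at 5.43 in adult and 5.54 in young IP (exact permutation test, adjusted p = 0.9165). That of the neuronal list was lower in adult IP, by -0.361 (exact permutation test, adjusted p = 0.0433). The myelin mean changed by -0.836 in the IP and by -0.729 in the supernatant, so its fall was not particular to the IP. Sexually dimorphic preoptic genes rose in 3 of 13 cases, also adjusted over the list alone, among them Ecel1 (0.97) and Calb1 (0.87; camera adjusted p = 0.00354, and adjusted p = 0.121 with an estimated correlation).

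In the IP of DHT mice (n = 6 each), Serpinb1a (3.19), Il33 (2.46), Atg7 (2.16), Kalrn (2.08) and Fasn, the fatty acid synthase gene (1.63), rose, and Cldn14, Nefl (-3.93), Kifc3 (-2.73) and Nefm (-2.14) fell. Gad1 (0.91) and Gad2 (0.97), the genes of the enzymes that make GABA, rose within a GABA system list of which 3 of 25 rose, 6 adjusted over the list alone (camera adjusted p = 2.88e-06, and adjusted p = 0.433 with an estimated correlation). Gal at 0.34 ± 0.28 and Kiss1 at 1.26 ± 0.45 did not pass the threshold there (edgeR adjusted p = 0.582 and 0.0882). Kiss1 did pass without adult DHT IP replicate 1 (1.49, edgeR adjusted p = 0.0185), the library at 2.41 CPM where the others stood at 12.6 to 31.9 CPM. Whether they changed differently after DHT was tested as an interaction, which gave -1.19 ± 0.41 for Gal and -1.37 ± 0.64 for Kiss1, neither past the threshold (edgeR adjusted p = 0.783 and 0.914). The IP gave 608 called genes in vehicle mice (324 higher, 284 lower) and 1131 in DHT mice (604 higher, 527 lower), with 158 higher and 175 lower in both treatments, where independent lists would share 12.3 and 9.42. Without the last 10 sample numbers 372 and 277 were called, with a term for them 713 and 672, and DESeq2 called 1149 and 1771. The overlap of the treatments was not recounted without those numbers.

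The age by treatment interaction called 0 genes in the IP, where 857 had an unadjusted p below 0.05 and DESeq2 called 50, and 0 in the supernatant, where 888 did and DESeq2 called 0. Voom called 0 in both. The gene with the smallest p in the IP was Scube3 (-7.02, edgeR adjusted p = 0.259). In the supernatant Aldh1l2 (-1.03), Luzp1 (0.46) and Nostrin (-1.14) led. Neuropeptide genes leaned lower in the supernatant interaction (median -0.54, camera adjusted p = 1.67e-07, and adjusted p = 0.446 with an estimated correlation), with 0 of 28 called over all genes and 2 lower adjusted over the list alone, and Tac2 at -1.31 ± 0.32. By direction, fry called 0 lists in either interaction.

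The fraction by age interaction in vehicle mice tested which genes changed with age differently in the IP and in its surroundings. Atg7 (log2 difference 2.18 ± 0.33), Kalrn (1.76) and Ubr3 (1.41) rose more in the IP. Nefl (-4.10 ± 0.28, edgeR adjusted p = 2.65e-14), Emilin1 (-7.70), Kifc3 (-3.04), Pom121 (-2.78), Nefh (-2.63 ± 0.52), Tcf20 (-2.54), Ubr4 (-2.45) and Srcin1 (-2.41) fell more in the IP. Gnrh1 stood at 0.79 ± 0.57 (edgeR adjusted p = 0.686) and Kiss1 at 0.44 ± 0.61 (edgeR adjusted p = 0.904). Oxidative phosphorylation genes leaned higher as a list (median 0.35, camera adjusted p = 8.77e-11, and adjusted p = 0.807 with an estimated correlation), with 1 of 32 called, Uqcrfs1, and 6 adjusted over the list alone. In all, 173 genes were called, 44 higher and 129 lower, against 105 (47 and 58) with the replicate block, 454 with DESeq2 and 90 with voom.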

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

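The test of non-specific pull-down in the enriched genes, the use of the replicate block in the test of GC content and length and for the genes that differed by age, the split by young IP level in the test of complexity, and the comparison of cell type means were chosen after the result was seen; the other tests here were not.

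Of the genes enriched at least 2-fold in the IP, 334 (59.43%) were at least 2-fold higher in the IP of the control without Cre, above the 12.36% of all tested genes, and Nefl reached 29998 CPM there. A shift shared by genes of like GC content and transcript length was argued against as the whole cause of the enrichment in Cre mice. Of 483 enriched genes with both values, 304 were at least 2-fold higher in the fit with the replicate block. After the median of their GC and length class was removed, 252 of these (82.9%, Clopper-Pearson interval 78.2% to 87.0%) stayed so, and 303 in all (62.7%, interval 58.2% to 67.1%) were. The largest median removed was 0.777 on the log2 scale, so strongly enriched genes could not fail. Ratios of the control were not corrected, so its overlap with the enriched genes was not tested for such a bias. The first run of this test, without the block, left 357 of the 483. Non-specific pull-down may account for much of this part of the enriched set, though the control is 1 library per fraction. Gnrh1, at 1.61-fold in the control against 146-fold in Cre mice, stands apart from it.

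The IP to supernatant ratio differed between adult and young vehicle mice for 173 genes by the interaction test, and for 129 of them it was lower in adults, but the replicate block gave 105 genes, 47 higher and 58 lower, with 44 of the 58 among the 129, so the excess of falls rests on the fit without it. Less non-specific pull-down in adult IP may contribute. Of the 129 genes, 33.33% (Clopper-Pearson interval 25.3% to 42.2%) were at least 2-fold higher in the young control IP. That compares with 12.36% of all tested genes and 4.55% of the 44 genes that were higher in adults. The share was 27 of 37 at 5 CPM or more in young vehicle IP. Under 5 CPM it was 16 of 92 (17.4%, interval 10.3% to 26.7%), close to that of all genes. With the block it was 32 of 58 (55.2%, interval 41.5% to 68.3%) against 2 of the 47 higher genes. Among the genes at least 2-fold higher in the IP of young vehicle mice it was 357 of 527 (67.7%). An excess could thus follow from any fall of genes high in young IP. No adult control was sequenced, so the adult background was not measured and the test cannot decide. Lower complexity of adult IP libraries, where it leaves a gene with no read, was argued against as the cause for the 37 genes at 5 CPM or more. There 2 of 185 values in adult vehicle IP (1.08%, interval 0.131% to 3.85%) were 0, and with the block 2 of 235 for 47 such genes. A fall to a few reads was not counted, so the test cannot decide for genes such as Emilin1, which fell from 35.5 to 0.108 CPM. For the 92 genes under 5 CPM, 73.9% of adult vehicle IP values (340 of 460) were 0, which is consistent with lower complexity and would also follow from a true fall, and the block left 11 such genes, with 29 of 55 values at 0. A change in GnRH neurons with age stays open and was not tested.

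Young libraries with the last 10 sample numbers (5 per fraction, of both treatments) differed from the other young libraries by 2092 genes in the IP and 3640 in the supernatant. Chance was excluded: of 100 splits, 1 gave as many genes in each fraction, the real one, and the highest other gave 7 in the IP and 2320 in the supernatant. A library batch is a candidate explanation, but a collection day, a difference in cell content or another tie of these numbers stays open, the labels name none of these, and no biological explanation was tested. Of 10 comparisons of cell type means, 5 per fraction, 2 did not overlap: microglial transcripts at 2.13 to 2.76 mean log2 CPM in these IP libraries against 1.05 to 2.01 in the other young ones, and neuronal transcripts at 8.29 to 8.49 against 8.58 to 8.69 in the supernatant. Xist was higher in these libraries (log2 fold change 1.83 in the IP and 1.94 in the supernatant, edgeR adjusted p = 0.0439 and 0.000881), but it stood at 0.696 to 18.1 CPM over the young vehicle IP libraries, and the annotation its count rests on is not given in the sources used here.

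One library stood far from its group in Gnrh1: replicate 6 of the young vehicle IP, at 6817 CPM, with the next library at 3514 CPM and the lowest at 1751 CPM. Chance would give 3.6 such libraries in the 72 sets of libraries examined, and 1 was found. The rule set the gap to the next library against the range of the group, so it can miss libraries in a widely spread group. Gnrh1 spread more widely in adult IP. It ran from 1951 CPM (replicate 2) to 16070 CPM in vehicle mice and from 663.6 CPM (replicate 2) to 13180 CPM in DHT mice.

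Chance could be excluded for the contrasts of fraction and of age, since of 100 splits of the libraries 1, the real one, gave as many genes in each. The real and highest other counts were 7684 and 2246 for the mean of the 4 conditions (2186 when labels were exchanged within replicate pairs, as the real split parts every pair), 3643 and 1 in young vehicle, 3324 and 0 in young DHT, 4002 and 1 in adult vehicle, and 3576 and 30 in adult DHT mice. They were 608 and 8 for age in vehicle IP, 1131 and 10 in DHT IP, 3301 and 814 in vehicle supernatant, 3248 and 447 in DHT supernatant, and 173 and 13 for the fraction by age interaction. For prenatal DHT in adult IP chance could not be excluded, since 42 of 100 splits gave at least the 1 gene called, and the highest other gave 796, so these libraries hold a structure, which was not identified. In the other DHT contrasts and the age by treatment interactions 0 genes were called, a count that all 100 splits reach in any data, so the splits say nothing of chance there. The highest other was 3 in young IP, 1 in adult supernatant, 57 and 59 among enriched genes in young and adult mice, and 141 and 1895 for the age by treatment interaction in IP and supernatant. In young supernatant it was 3829, in a split that put all 5 of the last sample numbers in 1 group. Without those numbers 39 genes were called between treatments there, and 0 with a term for them.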

How the results depend on the processing

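The fits without the last 10 sample numbers, and without genes high in the control IP, were chosen after the results were seen; the other alternatives were fixed beforehand. Counts that moved by over 1.5 times are given here, and no cause of these shifts was tested. Fits with fewer samples were not set against the removal of as many other samples. For IP against supernatant, voom called 5653 genes in young vehicle, leaving out the last 10 sample numbers called 1584 in young DHT, and fits of the compared groups alone called 2480 in adult vehicle and 2090 in adult DHT mice. For DHT in adult IP (1 gene), DESeq2 called 151, the term for the last sample numbers 3 and the fit without them 2, and voom, the compared groups alone and the replicate block 0; among enriched genes in adults DESeq2, no filter and the stricter filter each called 1. For DHT in young IP DESeq2 called 2. In young supernatant DESeq2 called 1 and the fit without the last sample numbers 39, and in adult supernatant voom and the replicate block 1 each. For age in vehicle IP (608), DESeq2 called 1149, voom 989, the replicate block 227 and the fit without the last sample numbers 372. In DHT IP (1131) DESeq2 called 1771, the term 672 and the fit without those numbers 277. In DHT supernatant (3248) the term gave 1919 and the fit without those numbers 1121. The age by treatment interaction called 50 in IP with DESeq2, and in supernatant 1 with the replicate block and 4 without the last sample numbers. The fraction by age interaction (173) called 454 with DESeq2, 90 with voom, 105 with the replicate block, 91 with the stricter filter and 89 without genes high in the control IP.

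Leaving out 1 library at a time gave 0 to 7 genes for DHT in adult IP, 0 to 2 among enriched genes in adults, 0 to 1 in adult supernatant, 313 to 553 for age in vehicle IP, 650 to 1355 in DHT IP, 0 to 1 for each age by treatment interaction and 87 to 250 for the fraction by age interaction. Counts moved most without young vehicle IP replicates 1 (313), 2 (399) and 4 (391) and adult vehicle IP replicate 2 (332) for vehicle IP. For DHT IP they did without young DHT IP replicates 2 (745) and 6 (650) and adult DHT IP replicates 2 (660) and 4 (736). For DHT in adult IP the count was 0 without adult DHT IP replicate 1 or 4, 5 without 5 and 3 without 6, and 2, 3, 4, 7 and 3 without adult vehicle IP replicates 1 to 5. Among enriched genes it was 2 without adult vehicle IP replicate 4 and 1 without replicate 5 or without adult DHT IP replicate 2, 3 or 5. It was 1 for DHT in adult supernatant and for the supernatant interaction without adult DHT supernatant replicate 6, and 1 for the IP interaction without adult vehicle IP replicate 3. For the fraction by age interaction it was 91, 114, 100, 105, 94 and 105 without young vehicle supernatant replicates 1 to 6, and 109, 93, 87 and 95 without adult vehicle supernatant replicates 1, 3, 4 and 5.

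Among named genes, 1 reversed: Esr2 between IP and supernatant stood at 0.20, -1.30 with voom and -1.22 with the replicate block, and the cause was not tested. Of the other values of named genes, DESeq2 kept 758 on the same side of the threshold, added 21 and lost 3, the replicate block added 6 and lost 23, and the fit without the last sample numbers lost 86. Kiss1, Il33, Mkrn3, Mobp and Cldn14 kept their calls for age in vehicle supernatant in all 20 alternatives, and Scube3 lost its call in 5 of 22, with adjusted p from 4.74e-12 to 0.497 over them. The numbers of vehicle and DHT mice, and of young and adult mice, are shared without a stated tie, so their block says nothing of pairing. Between fractions, where numbers tie an IP to its supernatant, the block changed calls of gene lists in single conditions (2 to 4 lists in young vehicle, adult vehicle and adult DHT mice, each lower in IP, as with the circadian clock at a camera adjusted p = 0.0352 against 0.0758 in adult vehicle) and of the striatum and septum list in the interaction (camera adjusted p = 0.0150 against 0.208), and the gene calls counted above. None of these list calls held with an estimated correlation, and beyond them and the values beside the results it changed no other call. Depth limits transcripts with few counts, but it does not set the zeros of the IP alone: 10.3% of tested genes were at 0 in adult vehicle IP and 5.93% in young vehicle IP at similar library totals.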

Other observations

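The set of genes described here was chosen after values were seen, and the test of it in the control is a description with no replicate.

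Of 376 transcripts enriched at least 2-fold at 5 CPM or more in the IP, 34 were no higher in the control IP than in its supernatant, in the only control pair there is. Among them were Rab25, a small GTPase gene (log2 fold change 6.18 ± 0.44, with 0.169 CPM in the supernatant), Epcam (5.52 ± 0.33) and F11r, a tight junction gene (2.41). They also held Pirt, a regulator of TRP channels (4.03 ± 0.38), Prph, the intermediate filament peripherin (2.59 ± 0.34), the BK channel subunit gene Kcnmb2 (2.04 ± 0.21) and the nicotinic receptor gene Chrna3 (1.01 ± 0.41). Cxcl14, a chemokine gene, was the most abundant of those named, at 178.5 CPM against 62.1 CPM (1.62 ± 0.15). In edgeR each of these passed the threshold, with Chrna3 the closest to it (adjusted p = 0.0393).

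Microglial genes rose with age in vehicle supernatant in 3 of 14 cases, also adjusted over the list alone, with Tmem119 at 0.67 (camera adjusted p = 0.00306, and adjusted p = 0.516 with an estimated correlation). Endothelial and mural cell genes fell in 4 of 15, also adjusted over the list alone, with Rgs5 at -1.21 and Cldn5 at -1.26 (camera adjusted p = 0.0123, and adjusted p = 0.575 with an estimated correlation). Neuropeptide and hormone receptor genes rose in 8 of 36, also adjusted over the list alone, with the prolactin receptor gene Prlr at 0.84, the growth hormone receptor gene Ghr at 0.53 and the melanocortin receptor gene Mc4r at 0.66 (camera adjusted p = 0.0121, and adjusted p = 0.385 with an estimated correlation). Among circadian clock genes 7 of 18 rose, 8 adjusted over the list alone, with Per2 at 0.82 (camera adjusted p = 0.00306, and adjusted p = 0.377 with an estimated correlation). None of these list calls held with an estimated correlation.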
